A study of Rattus norvegicus and Mus musculus with 14 samples.

How the data were processed

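Gene expression was measured on cDNA arrays of 1152 probes in 12 rat embryonic cortical neuron samples and 2 mouse cortex samples. Groups and replicate numbers came from the labels: control, NMDA and NMDA with PD98059 in the MEK set, control, NMDA and NMDA with nitroarginine in the NOS set, each with experiments 1 and 2, and 1 nNOS knockout and 1 wild-type littermate. The experiment number served as the replicate number.

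The deposited values are scores: every column has a mean of 0 (-0.0001 in 1 array) and most an SD near 1, so each array had been transformed to Z-scores. The SD was 0.967 in MEK set control replicate 1 and 0.857, 0.942 and 0.991 in the control, nitroarginine and NMDA arrays of NOS experiment 2, for a reason not given. How the authors made these scores is not given in the sources used here. The scale before that transform, the background correction and any filter are unknown, and no fold change can be recovered. Direction was taken as that of brightness, since it is not stated either. Column medians were 0.18, 0.13 and 0.15 in MEK experiment 1 (control, NMDA, PD98059), 0.24, 0.12 and 0.11 in MEK experiment 2, 0.06, -0.02 and -0.0008 in NOS experiment 1 (control, NMDA, nitroarginine), -0.08, -0.15 and -0.07 in NOS experiment 2, and -0.01 and -0.02 in the knockout and wild type. A Z-score per array removes any change common to all probes, and an array with a wider spread has its differences compressed. The tests had been designed for log2 values. Because the values are scores already normalized within arrays, the same limma fit was run on them as deposited.

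Of 1152 probes, 384 had 1 gene symbol in the platform annotation (342 genes), 6 had several and were not named, and 762 had none. Of the 384, 362 matched the rat gene table and the 22 others kept the annotation's symbol. The annotation is old and can be wrong for single clones. The 27 genes with more than 1 probe (up to 7) were tested by probe. Probes of the same gene can disagree, as for Akt1s1, Cand1, COX3, Gfap, Hspa8, Ldha, Ppp1r18, Rpsa and Sub1. No probe was named Nos1, Grin1, Fos, Arc, Egr1 or Bdnf.

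Values were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0): 6 group means over the 12 rat arrays, 6 residual degrees of freedom, empirical Bayes moderation, two-sided tests of 9 contrasts, Benjamini-Hochberg adjustment over 1152 probes and a threshold of 0.05. Mouse arrays stayed out of the fit. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a contrast, and with camera at an estimated correlation and fry beside it. Each probe of a member gene counted separately, though probes of 1 gene are not independent. Of 25 lists fixed before the data were examined, 10 had at least 3 genes measured: cytoskeleton and neurite, translation factors, chaperones, glycolysis, MAPK pathway genes, astrocyte markers, proteasome and ubiquitin, oxidative phosphorylation, calcium sensing and signalling, and ribosomal proteins. Another 9 had no member and 6 had 1 or 2 genes, and these were not tested. Random lists for percentiles were matched on mean level in 10 bins and drawn 10000 times. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

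Named genes followed a rule fixed before the data were examined. Per contrast these were the 10 largest differences each way among probes past the threshold with 1 symbol. Where under 5 passed in a direction, the probes with the smallest p filled up to 5 and are given by their values only. For the knockout they were the 10 largest differences each way among named probes brighter than the median probe. Genes taken from later settings are said to be chosen after their values were seen.

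The labels mark experiments 1 and 2 within each set, so experiment pairs the samples. Deviations from the group means of same-numbered arrays correlated at 0.874 to 0.930 in the NOS set and at -0.145 in the MEK set between NMDA and PD98059. The MEK set pairs that hold the misaligned control had -0.0386 and 0.0039. The fit without the block stayed the one designed.

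The column of MEK set control replicate 1 stands 1 row from its probes. As deposited it had r = 0.103 with the median array. Moved by 1 row it had 0.822, and the next best shift gave 0.213. Its 12 windows along the probe order had 0.786 to 0.930 with the other MEK set control. It was kept as deposited in the designed fit. Some alternatives were chosen after seeing the data. They moved that column, combined moving it or leaving it out with experiment as a block or with trend and robust moderation, crossed the PD98059 arrays, removed a running median over 25 probes along the probe order (with the block and without the misaligned array), or left out NOS experiment 2 together with the misaligned array (also alone, for the comparisons across sets and with the knockout). Alternatives fixed before the data were examined were quantile normalization, median centring, leaving out the dimmest 25% of probes, fixed and random blocks, trend with robust moderation, fewer groups, averaging probes of a gene, estimated correlation and each array left out.

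The fits were tested on simulated data for NMDA over both sets, with 50 of 1152 probes changed at each size. As designed with all columns aligned, 0% of changes of 0.3 Z units were recovered, 12% of 0.6, 62% of 1.2 and 96% of 2.4. With 1 control column moved by 1 row these were 0%, 0%, 52% and 90%. With the block and without that array they were 26%, 88%, 100% and 100%, with 7 false calls among 164. The simulated noise was independent between probes and had the spread of the block fit, equal in all experiments. Real NMDA differences were wider in NOS experiment 2 (SD 0.44) than in experiment 1 (0.13) and ran together along the probe order (lag 1 autocorrelation 0.496). The shares may therefore be too high for the real arrays.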

Results

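The series measured transcript abundance on a cDNA array in 14 samples. Of these, 12 were rat embryonic cortical neuron cultures in 2 sets. Each set held 2 experiments with 1 array per treatment. The treatments were a control solution that the labels call CSS, NMDA, and NMDA with an inhibitor. NMDA is an agonist of the NMDA class of glutamate receptor. In the MEK set the inhibitor was PD98059, which blocks the kinase MEK upstream of ERK. In the NOS set it was nitroarginine, which blocks nitric oxide synthase. The last 2 arrays were cortex of an adult mouse lacking neuronal nitric oxide synthase (nNOS) and cortex of a wild-type littermate. The values were Z-scores within each array, so differences are given in Z units, where 1 unit is about 1 SD over all probes of an array, and no fold change can be derived. Each rat group had n = 2 arrays and each mouse genotype had 1. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

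The 5 other MEK set arrays correlated with each other at r = 0.971 to 0.995 across probes, which are not independent replicates. The 3 arrays of NOS experiment 1 did so at 0.989 to 0.991. MEK set control replicate 1 stood apart, with r of -0.02 to 0.13 with the other arrays as deposited. When its column was moved by 1 row, its r with the median array was 0.822, and its r with the other MEK set arrays was 0.858 to 0.868. The 3 arrays of NOS experiment 2 correlated with those of NOS experiment 1 at only 0.454 to 0.617, and with each other at 0.894 to 0.937. In the NOS set, experiment accounted for 86.9% of the variance between arrays and treatment for 6.77%. In the 5 aligned MEK set arrays the shares were 15.8% and 69.2%, but the control is then 1 array, whose own deviation cannot be separated from treatment, so these shares are not comparable with those of the NOS set. The comparisons below use all 12 rat arrays as deposited, as fixed before the data were examined. Leaving out each array in turn, the misaligned one included, was fixed then too. Moving that column, leaving it out together with a block or other steps, and leaving out NOS experiment 2 were added after seeing the data.

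**Figure D1:**
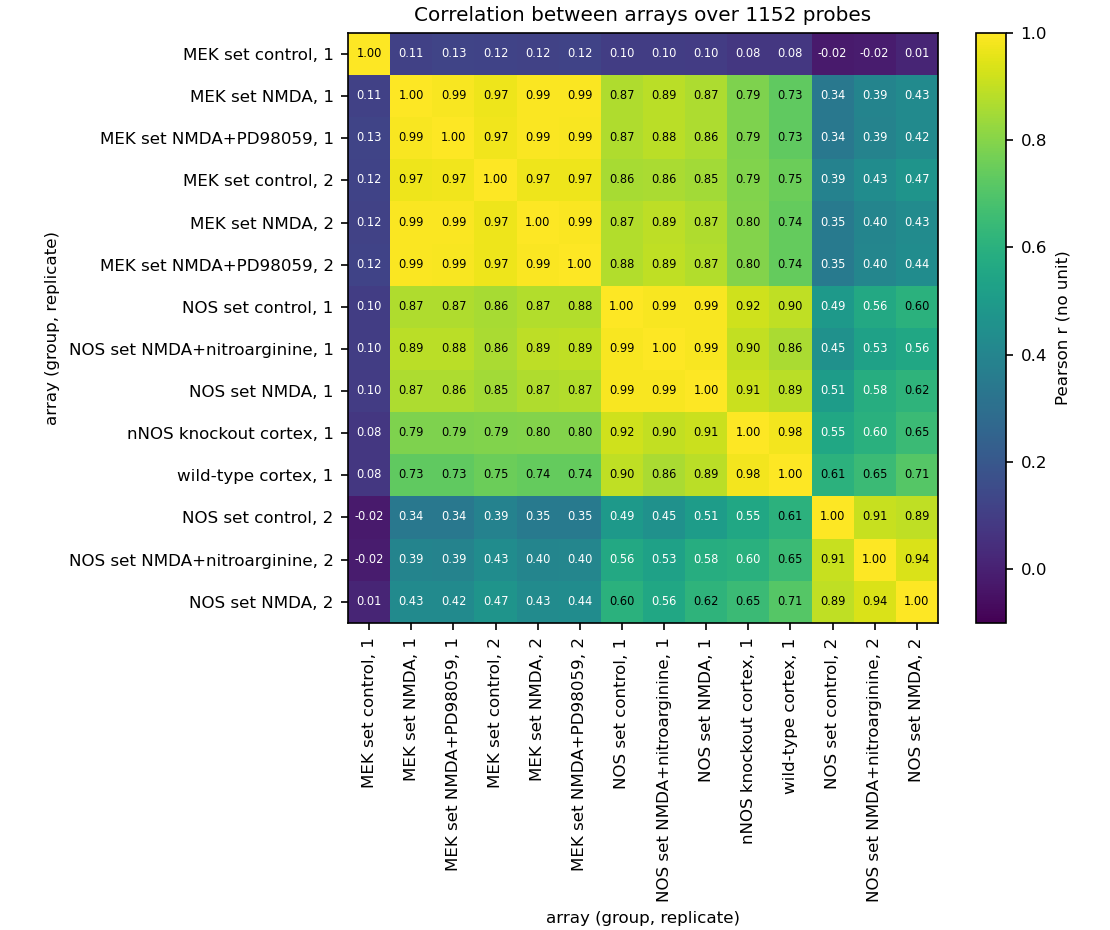
Pearson correlation (no unit, colour scale from -0.1 to 1) between each pair of the 14 arrays over all probes, with rows and columns ordered by set and experiment. MEK set control replicate 1 reaches at most 0.13 with another array, and the 3 arrays of NOS experiment 2 form a block of their own at 0.89 to 0.94.

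NMDA was compared with control over both sets to ask what the agonist did to the cultures (n = 4 arrays each). As designed, 1 of the 4 controls is the misaligned column, so each value is in part a difference between unlike probes. Among probes with a gene name, lower values under NMDA were those of Golm2, at -0.98 Z units (SE 0.34), Akt1s1, a subunit of mTORC1 that restrains it, at -0.66 (SE 0.29) on 1 probe and -0.12 on the other, Ncln at -0.62 (SE 0.24), Mapk8, the kinase JNK1, at -0.55 (SE 0.25), and Dpysl5, a collapsin response mediator family protein of growth cones, at -0.48 (SE 0.22). Higher values were those of COX3, a mitochondrially encoded subunit of cytochrome c oxidase, at 0.77 (SE 0.41), the zinc finger gene Zfp763 at 0.71 (SE 0.38), Ppp4r1, a regulatory subunit of protein phosphatase 4, at 0.53 (SE 0.32), Cand1, a regulator of cullin ubiquitin ligases, at 0.45 (SE 0.27), and Etnk1, an ethanolamine kinase, at 0.44 (SE 0.25). None passed, with adjusted p = 0.952 in limma for each. Limma placed 0 probes past the threshold, and 6 had an unadjusted p under 0.05 where 57.6 would by chance. With experiment as a block and the misaligned column moved by 1 row, limma also called 0 probes. In that added setting 128 probes had an unadjusted p under 0.05. Without MEK set control replicate 2, which leaves the misaligned column as the only MEK set control, Golm2 was at -1.39. With experiment as a block and the misaligned array left out, the values were 0.29 for COX3, 0.21 for Zfp763, 0.22 for Ppp4r1, 0.17 for Cand1, -0.57 for Golm2 and -0.41 for Akt1s1. Other probes of COX3 ran from -0.23 to 1.14 as designed, and those of Cand1 from -0.27 to 0.15.

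Cytoskeletal and neurite genes were higher under NMDA in 12 of 15 probes, with a median of 0.18 Z units, which did not pass (camera, adjusted p = 0.133; adjusted p = 0.383 with an estimated correlation). The 15 probes are of 11 genes. Repeat probes, such as those of Actb, are not independent members, so probe counts and p-values at the preset correlation overstate the breadth. Without the misaligned array, MEK set control replicate 1, the list rose in 14 of 15 probes with a median of 0.13 (camera, adjusted p = 0.0106). With experiment also a block, the estimated correlation ended the call (adjusted p = 0.609 with an estimated correlation), and so did leaving out NOS experiment 2 too (adjusted p = 0.242). Over all settings and arrays left out, the adjusted p ran from 0.00132 to 0.764, and the list passed only in settings that left out or moved the misaligned array. Of its members, chosen after their values were seen, Tuba1a, an alpha-tubulin, was higher by 0.54, 0.21 and 0.45 Z units in MEK experiment 2, NOS experiment 1 and NOS experiment 2. Nefl, the neurofilament light chain, was higher by 0.64, 0.08 and 0.24. As designed, 0 members passed adjusted over the list alone, and 2 did with the block and without the misaligned array.

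**Figure D2:**
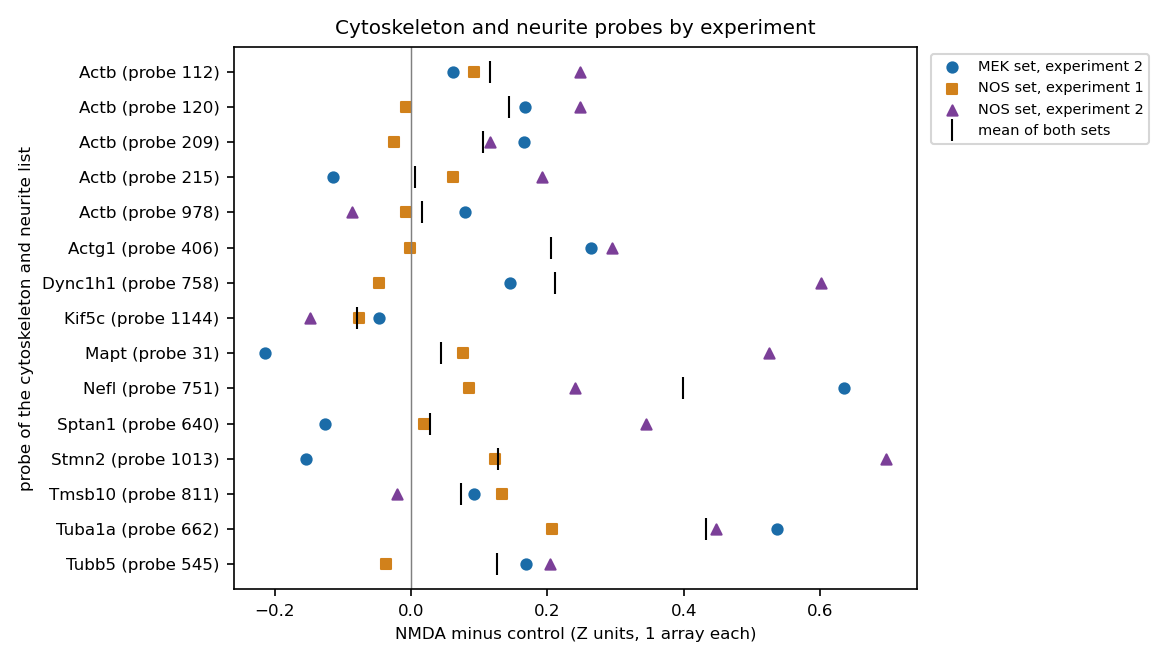
NMDA minus control in Z units (horizontal axis) for the 15 probes of the cytoskeleton and neurite list (vertical axis), with 1 point per experiment whose control column is aligned and a black bar for the mean of both sets without the misaligned array. The black bars of 14 of 15 probes lie above 0, while single experiments scatter to both sides of 0.

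The other 9 lists did not pass for NMDA over both sets as designed (camera). Translation factors were higher in 9 of 12 probes (median 0.22, adjusted p = 0.366), chaperones in 5 of 8 (0.11, 0.718) and glycolytic enzymes in 4 of 5 (0.09, 0.762). These probes are of only 6, 4 and 4 genes, in that order. With the trend along the probe order removed, a setting added after seeing the data, chaperones rose in 8 of 8 probes (median 0.17, adjusted p = 0.0315; range over all settings and arrays left out 0.0315 to 0.994). The adjusted p was 0.771 for the MAPK pathway genes Etv5, Grb2 and Map2k2 (median 0.05), the astrocyte markers (0.02), proteasome and ubiquitin genes (0.16), oxidative phosphorylation (-0.10) and calcium sensing and signalling (-0.15). It was 0.846 for ribosomal proteins (median 0.03). All these medians as designed include the misaligned column. Without it, oxidative phosphorylation probes were at 0.16 (Atp5f1a), 0.08 (Atp5pb), -0.16 (Ndufaf1) and 0.09 (Atp5mc1). Glycolysis probes were then at 0.004 (Pkm), 0.09 (Pgk1), -0.23 and 0.03 (Ldha) and -0.21 (Gapdh). With the block too, the directional fry test turned from down to up for oxidative phosphorylation and from up to down for glycolysis. Adjusted over the list alone, 0 members of any list passed.

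In 1 of the 7 settings added after seeing the data, 1 of which equals leaving out the misaligned array in turn, limma called 13 probes for NMDA over both sets, 10 higher and 3 lower. That setting had experiment as a block, the misaligned array left out and a variance trend with robust moderation. Uchl1, a neuronal ubiquitin hydrolase, rose by 0.32 Z units (SE 0.07, adjusted p = 0.0296), with 0.27, 0.34 and 0.31 in the 3 experiments with an aligned control. Its other probe was not called and was at 0.44, -0.005 and 0.67. Vars, valyl-tRNA synthetase, fell by 0.58 (SE 0.12, adjusted p = 0.0296), with -0.76, -0.37 and -0.26. The other 11 probes have no gene name here. Without the trend and robust steps, limma called 0 probes, with 82 at an unadjusted p under 0.05.

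Within the MEK set, NMDA against control (n = 2 each) gave -1.35 Z units for Golm2 (SE 0.49), -1.25 for Akt1s1 (SE 0.40), -1.22 for Rraga, a GTPase that activates mTORC1 (SE 0.49), -1.04 for the SNARE gene Snap23 (SE 0.39) and -0.79 for Dpysl5 (SE 0.31). Higher values were those of Map7d1, a microtubule-associated protein gene, at 1.52 (SE 0.76), Zfp763 at 1.33 (SE 0.54), Hes6, a helix-loop-helix transcription regulator, at 1.195 (SE 0.62), the growth factor gene Igf2 at 1.15 (SE 0.59) and COX3 at 1.11 (SE 0.58). None passed, with adjusted p = 0.626 in limma for each. No probe was called by limma (0), and 25 had an unadjusted p under 0.05. Without MEK set control replicate 2 it called 349 probes, with Map7d1 at 3.05. With the block and the misaligned array left out, the values were -0.01 for Map7d1, 0.33 for Zfp763, 0.15 for Hes6, 0.06 for Igf2, 0.15 for COX3, -0.52 for Golm2, -0.75 for Akt1s1, -0.34 for Rraga, -0.60 for Snap23 and -0.85 for Dpysl5. As designed, other probes of COX3 ran from -0.89 to 2.27, and the other Akt1s1 probe was at -0.11. The misaligned column is 1 of the 2 controls in the designed fit, so each designed value is in part a difference between unlike probes. The SD of the differences over probes was 0.674 as designed and 0.232 without that array.

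With the misaligned array and NOS experiment 2 left out, limma called 82 probes for NMDA in the MEK set, 7 higher and 75 lower. The MEK set control was then 1 array, assumed to vary like the other groups, with 2 residual degrees of freedom. That array had a median of 0.24, against 0.12 in the NMDA array of MEK experiment 2. The surplus of lower probes cannot be told apart from the shape of that 1 column. Among 25 named probes, Dpysl5 fell by 0.87 Z units (SE 0.12, adjusted p = 0.0195), Akt1s1 by 0.78 and by 0.72 on 2 probes, Vars by 0.75, Anxa1, a calcium-dependent phospholipid-binding protein, by 0.72, Adpgk, an ADP-dependent glucokinase, by 0.67, Ldha, a lactate dehydrogenase subunit, by 0.63 on 1 probe (the other, not called, was at -0.02 in MEK experiment 2), the transcription factor gene Mef2d by 0.60 and the initiation factor gene Eif4b and Cand1 by 0.57. This Cand1 probe is not the one above, and its 2 other probes, not called, were at 0.10 and -0.22 in MEK experiment 2. Tmpo, a nuclear lamina-associated protein gene, rose by 0.46 and Fbn1, encoding fibrillin, by 0.39. Of the 82 probes, 56 had the same sign in NOS experiment 1 and 35 in NOS experiment 2. Over all probes, the sign of MEK experiment 2 was shared by 57.2% in NOS experiment 1 and 43.8% in NOS experiment 2. None of the 10 lists passed in the MEK set as designed. The lowest adjusted p was 0.735, which cytoskeletal genes shared (11 of 15 higher, median 0.23). Chaperones had a median of -0.16, a mean of 0.10 and a test that pointed up, astrocyte markers -0.18, 0.11 and a test that pointed down, and ribosomal proteins a positive median (0.05) with a test that pointed down.

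Within the NOS set, the calcium sensing and signalling list was lower under NMDA than under control (n = 2 each), in 3 of 3 probes with a median of -0.38 Z units (camera, adjusted p = 0.00202; adjusted p = 0.108 with an estimated correlation). Its members are Hpca, a neuronal calcium sensor, Ncald, another of that family, and Prkca, a protein kinase C. In NOS experiment 2 they were at -0.91, -0.65 and -0.54, and in experiment 1 at -0.14, -0.11 and 0.02. Without NOS experiment 2 and the misaligned array the median was -0.11 (adjusted p = 0.612). The call was also lost when any 1 of the 4 arrays was left out, and with a trend along the probe order removed (adjusted p = 0.204, median -0.07). With 1 array out and no block, the contrast also holds the difference between experiments. The SD of the differences over probes then rose from 0.23 to between 0.46 and 0.58. Losing the call in this way cannot separate a weak call from that difference. Over all settings and arrays left out, the adjusted p ran from 0.00202 to 0.988. With that trend removed, chaperones (7 of 8 probes higher, median 0.15, adjusted p = 0.0297; range 0.0297 to 0.988) and cytoskeletal genes (14 of 15, 0.10, 0.0145; range 0.0145 to 0.988) rose instead. Adjusted over the list alone, 0 members passed.

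Other named probes of the NOS set under NMDA were Ncln at -0.69 Z units (SE 0.35), Mapk8 at -0.62 (SE 0.35), Tmcc2 at -0.59 (SE 0.40), the endocytic adaptor gene Eps15 at -0.51 (SE 0.34) and the splicing factor gene Sfrs2 at -0.38 (SE 0.29). Cand1 was at 0.49 (SE 0.38), the transcription coactivator gene Sub1 at 0.47 (SE 0.37), Gfap, an astrocyte intermediate filament gene, at 0.42 (SE 0.29), the autophagy gene Atg2a at 0.38 (SE 0.31) and Rap1gap at 0.35 (SE 0.31). All 10 were farther from 0 in NOS experiment 2 than in experiment 1. In experiments 1 and 2, Ncln was at -0.16 and -1.22, Mapk8 at -0.13 and -1.10, Tmcc2 at -0.23 and -0.96, Eps15 at -0.15 and -0.87, Sfrs2 at -0.03 and -0.74, Cand1 at 0.30 and 0.68, Sub1 at 0.05 and 0.89, Gfap at 0.19 and 0.65, Atg2a at 0.02 and 0.75, and Rap1gap at 0.12 and 0.57. The other probes were at 0.05 for Sub1, 0.12 for Gfap, and 0.21 and 0.12 for Cand1 over both experiments. As designed, limma passed 0 probes and 0 had an unadjusted p under 0.05, where 57.6 would by chance. That fit leaves the difference between experiments in its spread. With the block limma also passed 0 probes. Then 100 probes had an unadjusted p under 0.05 without the misaligned array, and 57 with its column moved. Cytoskeletal genes were higher in 13 of 15 probes (median 0.15, adjusted p = 0.0762) and translation factors in 10 of 12 (0.13, 0.0848). MAPK pathway genes had a positive median (0.05) and a negative mean (-0.09).

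The difference between the sets in the NMDA effect was tested as an interaction, which as designed also holds the misaligned column. NOS minus MEK values were 1.35 Z units for Rraga (SE 0.69), 1.33 for a COX3 probe (SE 0.69) other than the one above, which was at -0.68, 1.18 for Akt1s1 (SE 0.57), 1.02 for the ribosomal protein gene Rpsa (SE 0.46) and 0.82 for Stx7, a SNARE of late endosomes (SE 0.44). Values were -1.53 for Mtcp1 (SE 1.05), -1.38 for Pqbp1 (SE 0.90), -1.32 for Hes6 (SE 0.88), -1.24 for Zfp763 (SE 0.77) and -0.85 for Ncald (SE 0.49). None passed (limma, 0 calls, adjusted p = 0.972 for each), and 3 probes had an unadjusted p under 0.05. Without MEK set control replicate 2 limma called 138, with Rraga at 2.22. With the block and the misaligned array left out, the values were 0.47 for Rraga, 0.53 for COX3, 0.68 for Akt1s1, 0.66 for Rpsa, 0.63 for Stx7, -0.17 for Mtcp1, -0.47 for Pqbp1, -0.28 for Hes6, -0.23 for Zfp763 and -0.42 for Ncald. Without the misaligned array and NOS experiment 2, Mtcp1 was at 0.03, Ncald at -0.17, Rraga at 0.25 and Akt1s1 at 1.09. As designed, the other Rpsa probe was at -0.12, the other Akt1s1 probe at -0.01, and the other 6 COX3 probes ran from -2.27 to 0.81. No list passed. The calcium list had a median of -0.56 (adjusted p = 0.254), and -1.01 without NOS set control replicate 1, where it passed (adjusted p = 0.0416; range over all settings and arrays left out 0.0416 to 0.914). MAPK pathway genes had a positive median (0.02) and a negative mean (-0.41), and ribosomal proteins a negative median (-0.03) and a positive mean (0.13).

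PD98059 was compared with NMDA alone in the MEK set to ask what MEK inhibition did to stimulated cultures (n = 2 each). Lower values were those of Hspa8, the constitutive Hsc70 chaperone, at -0.41 Z units (SE 0.37) with its 4 other probes from -0.03 to 0.08, Hpca at -0.36 (SE 0.42), the transcriptional repressor gene Cic at -0.35 (SE 0.46), Ppp1r18 at -0.31 (SE 0.36) and Eepd1 at -0.26 (SE 0.30). Higher values were those of the ribosomal protein gene Rpl13 at 0.14 (SE 0.48), Dlg4, the postsynaptic scaffold PSD-95, at 0.09 (SE 0.30), the creatine transporter gene Slc6a8 at 0.08 (SE 0.30), Atg2a at 0.08 (SE 0.31) and the purine synthesis gene Paics at 0.07 (SE 0.28). The other Ppp1r18 probe was at 0.03. The count in limma was 0, and 0 probes had an unadjusted p under 0.05. The SD of the difference over probes was 0.088 against a median SE of 0.474, which pools the spread of all 12 rat arrays. With the groups of this contrast alone, the median SE was 0.065, and limma called 0 probes with 47 at an unadjusted p under 0.05 where 57.6 would by chance. The calcium and chaperone lists had adjusted p = 0.124, and the chaperones had a positive median (0.02) with a negative mean (-0.06), as had the cytoskeletal genes (0.007 and -0.04). Without MEK set NMDA replicate 2 the chaperones fell, with 3 of 8 probes higher and a median of -0.05 (camera, adjusted p = 0.0275; range over all settings and arrays left out 0.0275 to 0.991). The PD98059 differences of both experiments correlated at r = -0.11 across probes (rho -0.32), with the same sign in 36.9% and 1 of 1104 rotations of the probe order as large. The experiments thus tended to run opposite to each other, across probes that are not independent replicates.

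PD98059 with NMDA against control gave -1.35 Z units for Golm2 (SE 0.49), -1.34 for Safb2 (SE 0.54), -1.24 for Akt1s1 (SE 0.40), -1.03 for Snap23 (SE 0.39) and -0.89 for the topoisomerase gene Top1 (SE 0.36). It gave 1.51 for Map7d1 (SE 0.76), 1.28 for the neural adhesion gene Ntm (SE 0.64), 1.14 for Igf2 (SE 0.59), 1.13 for Zfp763 (SE 0.54) and 0.76 for Cand1 (SE 0.39). None passed (limma, 0 calls, adjusted p = 0.643 for each), and 19 probes had an unadjusted p under 0.05. It called 338 without MEK set control replicate 2, with Map7d1 at 3.04. It called 76, 12 higher and 64 lower, without the misaligned array and NOS experiment 2, where the control was 1 array. With the block and the misaligned array left out, the values were -0.02 for Map7d1, 0.18 for Ntm, 0.05 for Igf2, 0.12 for Zfp763, 0.20 for Cand1, -0.52 for Golm2, -0.46 for Safb2, -0.74 for Akt1s1, -0.58 for Snap23 and -0.37 for Top1. As designed, other probes of Cand1 were at -0.16 and -0.64, and the other Akt1s1 probe was at -0.04. The designed values here too are in part differences between unlike probes, through the misaligned control column. No list passed as designed. Chaperones had a median of -0.10 and a mean of 0.03, and astrocyte markers -0.20 and 0.10.

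Nitroarginine was compared with NMDA alone in the NOS set to ask what nitric oxide synthase inhibition did to stimulated cultures (n = 2 each). Lower values were those of Dmxl2, a synaptic vesicle-associated protein gene, at -0.47 Z units (SE 0.29), Stx7 at -0.43 (SE 0.31), Atg2a at -0.43 (SE 0.31), Polr2m at -0.43 (SE 0.34) and Gfap at -0.39 (SE 0.29). Higher values were those of Poll, a DNA repair polymerase gene, at 0.49 (SE 0.35), the splicing gene Son at 0.41 (SE 0.45), Ncln at 0.38 (SE 0.35), the protease gene Tmprss5 at 0.37 (SE 0.31) and Sfrs2 at 0.34 (SE 0.29). By limma 0 probes passed and 0 had an unadjusted p under 0.05, where 57.6 would by chance. With the block limma also passed 0 probes. Then 74 probes had an unadjusted p under 0.05 without the misaligned array, and 42 with its column moved. All 10 named probes were farther from 0 in NOS experiment 2 than in experiment 1. In experiments 1 and 2, Dmxl2 was at -0.18 and -0.75, Stx7 at -0.16 and -0.70, Atg2a at -0.22 and -0.64, Polr2m at -0.17 and -0.69, Gfap at -0.07 and -0.70 (its other probe at -0.16 and 0.39), Poll at 0.08 and 0.90, Son at 0.17 and 0.66, Ncln at 0.16 and 0.61, Tmprss5 at 0.15 and 0.58, and Sfrs2 at 0.17 and 0.50. Over all probes the nitroarginine differences of both experiments correlated at r = 0.19 (rho 0.22), with the same sign in 60.9% and 0 of 1104 rotations of the probe order as large. Probes are not independent replicates. Cytoskeletal genes were higher in 3 of 15 probes (median -0.08, camera, adjusted p = 0.737), and no list passed. With the trend along the probe order removed, the cytoskeletal list fell (median -0.07, adjusted p = 0.0363; range over all settings and arrays left out 0.0363 to 0.977). Medians of proteasome (-0.01) and ribosomal protein genes lay below 0 with means of 0.03, and chaperones (-0.02) had a test that pointed up. The oxidative phosphorylation list had a negative median (-0.03) with a mean near 0. Its fry test for change in either direction did not pass as designed (unadjusted p = 0.990). With the block and without the misaligned array, a setting added after seeing the data, that fry test passed (adjusted p = 0.00368). The directional fry test of that setting did not (adjusted p = 0.985).

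With nitroarginine and NMDA against control, translation factors were higher in 10 of 12 probes with a median of 0.18 Z units (camera, adjusted p = 0.0185; adjusted p = 0.123 with an estimated correlation). These 12 probes are of 6 genes, so probes of the same gene count more than once. The calcium list was lower in 3 of 3 probes with a median of -0.25 (camera, adjusted p = 0.0185; adjusted p = 0.123 with an estimated correlation). Without NOS experiment 2 and the misaligned array the medians were 0.08 (adjusted p = 0.348) and -0.03 (adjusted p = 0.863). Both calls were lost when any 1 of the 4 arrays was left out, which also puts the difference between experiments into the contrast. Quantile normalization ended the translation call (adjusted p = 0.0999), and the block without the misaligned array ended the calcium call (adjusted p = 0.0609). Over all settings and arrays left out, the adjusted p ran from 0.0132 to 0.899 for translation and from 0.0151 to 0.899 for calcium. Ribosomal proteins were higher in 7 of 8 probes (median 0.18, adjusted p = 0.0771), and passed with quantile normalization (adjusted p = 0.0213) and with the trend along the probe order removed (adjusted p = 0.0234; range over all settings and arrays left out 0.0213 to 0.899). Named probes were Pbxip1 at 0.56 (SE 0.70), Poll at 0.37 (SE 0.35), Hspa8 at 0.36 (SE 0.35) with other probes from -0.18 to 0.29, the phosphate exporter gene Xpr1 at 0.35 (SE 0.35) and Eif4g1, a translation initiation scaffold, at 0.23 (SE 0.30). Lower were Mapk8 at -0.61 (SE 0.35), Golm2 at -0.59 (SE 0.49), the neuronal adhesion gene Dscam at -0.57 (SE 0.36), Tmcc2 at -0.51 (SE 0.40) and Sez6 at -0.42 (SE 0.36). Without NOS experiment 2 and the misaligned array the direction turned for Dscam (0.06), Sez6 (0.04), Poll (-0.01) and Xpr1 (-0.11), and the others were at 0.16 (Pbxip1), 0.09 (Hspa8), 0.04 (Eif4g1), -0.20 (Mapk8 and Golm2) and -0.18 (Tmcc2). Limma called 0 probes and 0 had an unadjusted p under 0.05, and 0 list members passed adjusted over the list alone. With the block limma also called 0 probes. Then 68 probes had an unadjusted p under 0.05 without the misaligned array, and 43 with its column moved, where 57.6 would by chance.

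The inhibitors were set against each other as nitroarginine minus its NMDA group less PD98059 minus its NMDA group. Values were 0.74 Z units for Chpf, a chondroitin synthesis gene (SE 0.79), 0.69 for Poll (SE 0.49), 0.64 for Hpca (SE 0.59), 0.61 for the co-chaperone gene Dnaja1 (SE 0.65) and 0.57 for the clathrin adaptor gene Ap2m1 (SE 0.67). They were -0.51 for Atg2a (SE 0.44), -0.49 for Dmxl2 (SE 0.41), -0.48 for Stx7 (SE 0.44), -0.46 for Polr2m (SE 0.49) and -0.42 for Gfap (SE 0.41), whose other probe was at 0.15. Without NOS experiment 2 and the misaligned array they were at 0.33 for Chpf, 0.28 for Poll, 0.46 for Hpca, 0.50 for Dnaja1, 0.35 for Ap2m1, -0.30 for Atg2a, -0.21 for Dmxl2 and Stx7, -0.20 for Polr2m and -0.10 for Gfap. In limma 0 probes passed and 0 had an unadjusted p under 0.05. With the block and without the misaligned array 0 passed and 16 had an unadjusted p under 0.05. A difference that misses the threshold with a median SE of 0.671 does not show that the inhibitors act alike. No list passed. Chaperones had a median of -0.08 with a mean of 0.06, and glycolytic enzymes 0.07 with -0.03.

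Reversal of the NMDA differences was tested without shared arrays, on the 50 probes farthest in each direction under NMDA in the other set. On the 50 highest in the NOS set, PD98059 had a median of 0.01 Z units (SD between experiments 0.02), at percentile 31.8 among 10000 random lists matched on level. On the 50 lowest it had a median of 0.02 (SD 0.04), at percentile 43.0. On the 50 highest in the MEK set, nitroarginine had a median of -0.01 (SD 0.03), at percentile 78.8, and on the 50 lowest 0.09 (SD 0.14), at percentile 90.4. The choice of MEK set probes includes the misaligned column. Their median NMDA differences were 1.407 and -1.221, while the SD over probes in MEK experiment 2 was 0.24. The NOS set choice leans on NOS experiment 2, where that SD was 0.44 against 0.13 in experiment 1. Limma passed 0 probes for NMDA in each set, so medians near 0 cannot separate a lack of reversal from a lack of response. Leaving out the misaligned column moved the nitroarginine medians to 0.07 on the highest and -0.01 on the lowest probes. On the lowest probes, leaving out NOS experiment 2 turned the median to -0.04 (percentile 1.03), and leaving out both to -0.05 (percentile 0.12). With any 1 array left out, the nitroarginine medians ran from -0.38 (without NOS set NMDA replicate 2) to 0.48 (without NOS set nitroarginine replicate 2) on the highest probes, and from -0.20 to 0.36 on the lowest. The ends of these ranges each left out 1 NOS set array, so they also hold the difference between experiments.

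For the nNOS knockout, no probe carries the name of the targeted gene, Nos1, so the genotype labels could not be checked. With 1 array per genotype there is no replicate check and no p-value. Higher in the knockout were Fbn1 by 0.52 Z units, Uchl1 by 0.42 on 1 probe and 0.19 on the probe named under NMDA, the calcium channel subunit gene Cacnb1 by 0.40, Rpsa by 0.36, the beta-tubulin gene Tubb5 by 0.36, Macf1 by 0.34, Bcat1 and Zfp706 by 0.31, and the adaptor gene Grb2 and Mcrs1 by 0.30. Lower were Slc6a8 at -0.76, Dpysl5 at -0.63, the splicing factor gene Sf3a3 at -0.50, Mrpl37 at -0.46, Rraga at -0.45, Eepd1 at -0.44, the GABA-B receptor gene Gabbr1 at -0.40, Nppa at -0.38, COX3 (another probe than under NMDA) at -0.37 and Ankrd28 at -0.35. The other probes were at 0.03 for Bcat1, 0.11 for Grb2 and -0.02 for Rpsa, and those of COX3 ran from -0.32 to 0.04. The arrays correlated at r = 0.980 across probes, and the SD of the differences was 0.199. Proteasome and ubiquitin genes were higher in 4 of 4 probes (median 0.20, percentile 98.04 among random lists matched on level), and ribosomal proteins in 5 of 8 (0.13, 95.3). The 4 proteasome and ubiquitin probes are of 3 genes, with the Uchl1 probes above among them. Their percentile is the highest of the 10 lists and is not adjusted. Percentiles over probes do not measure the spread between animals. The other lists had percentiles of 29.8 (calcium, median -0.08), 30.2 (oxidative phosphorylation), 32.9 (cytoskeleton), 45.3 (chaperones), 47.2 (translation), 49.8 (glycolysis), 53.3 (MAPK) and 71.3 (astrocyte).

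Loss of nNOS was set against its inhibition. The knockout differences correlated with the nitroarginine minus NMDA differences at r = 0.30 (Spearman's rho 0.34), with the same sign in 64.5% of probes. This is a correlation across probes, which are not independent replicates. It was 0.50 with NOS experiment 1 (rho 0.56) and 0.15 with experiment 2 (rho 0.20). Over 1104 rotations of the probe order the highest absolute r was 0.16 and 0.14. Of the 20 knockout genes above, 19 had the same sign under nitroarginine in experiment 1 and 9 in experiment 2, against 74.4% and 60.3% of all probes. Genes chosen for a large knockout difference share sign more often than all probes wherever the differences correlate. Such a high count therefore adds nothing to r. Fbn1 (0.52 in the knockout) was at 0.19 and 0.39 under nitroarginine, Rpsa (0.36) at 0.13 and 0.30 (its other probe, at -0.02, at 0.02 and -0.10), and Nppa (-0.38) at -0.31 and -0.32. Uchl1 (0.42) was at 0.18 and -0.47. The knockout differences also correlated at 0.36 with NMDA minus control of MEK experiment 2 (rho 0.33), where 19 of the 20 genes and 62.3% of all probes had the same sign with no NOS inhibitor. With the other 4 differences that involve no NOS inhibitor r was -0.04 and -0.15 (NMDA minus control, NOS experiments 1 and 2) and -0.008 and -0.03 (PD98059 minus NMDA, MEK experiments 1 and 2).

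**Figure D3:**
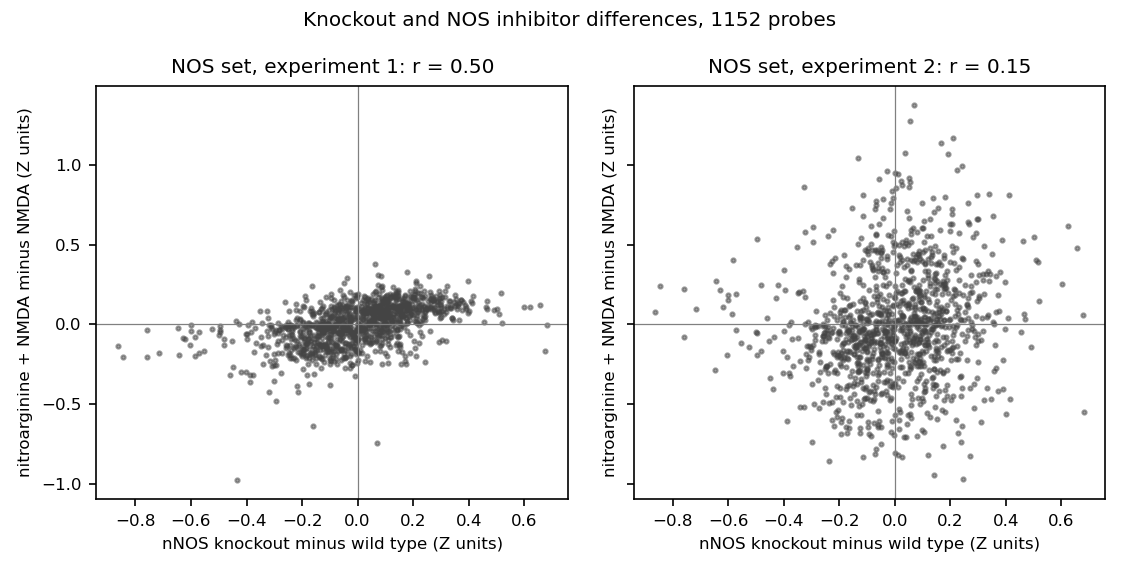
Knockout minus wild-type difference (horizontal, Z units) against nitroarginine with NMDA minus NMDA difference (vertical, Z units) for all probes, 1 panel per NOS experiment on shared axes. The points follow each other at r = 0.50 in experiment 1 and 0.15 in experiment 2, where the vertical spread is wider.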

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

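Settings that move the misaligned array, combine moving it or leaving it out with the replicate block, remove the position trend, cross the PD98059 arrays or leave out NOS experiment 2 were chosen after seeing the data. The others were fixed before, including each array left out in turn, which covers leaving out the misaligned one alone. Over all results that answer a comparison, 352 values kept their count or stayed within the spread between experiments and 48 did not. Among named probes and called lists 1826 values kept sign and side of the threshold, 38 passed only in an alternative, 27 list values no longer passed, and 27 changed sign. A limma count of 0 that stayed 0 counted as kept, and so did a named value that shrank but held its sign. As designed the limma count was 0 in all 9 contrasts, so these tallies say little about robustness. The alternative with another floor was not run because the values are not linear. No signal over background is given. On simulated data, 62% of changes of 1.2 Z units were recovered as designed, 52% with a control column moved by 1 row, and 100% with the block and without that array. These data had independent noise taken from the block fit, so the shares may be too high for the real arrays.

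Replicate block and pairing. With experiment as a block on all 12 arrays, limma called 0 probes in every contrast, as it did without, and the calcium and translation list calls held. Crossing the PD98059 arrays (correlation -0.145 between the MEK set NMDA and PD98059 deviations) gave 0 calls in the 3 PD98059 contrasts, with 10, 59 and 19 at an unadjusted p under 0.05.

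Probes called by limma went from 0 to 13 for NMDA over both sets (block, misaligned array out, trend and robust), and from 0 to 82 for NMDA in the MEK set and to 76 for PD98059 against control (misaligned array and NOS experiment 2 out). Leaving out 1 array each time, the counts ran from 0 to 184 for NMDA over both sets, 0 to 349 in the MEK set, 0 to 338 for PD98059 against control and 0 to 138 for the NMDA difference between sets. Each upper end left only the misaligned column as MEK set control, and by construction the difference is then between unlike probes.

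Lists called for NMDA over both sets went from 0 to 1 with the misaligned array out or moved, each with and without the block, and to 2, cytoskeleton and chaperones, with the position trend removed. For NMDA in the NOS set the 1 call became 0 with both estimated correlation settings and with NOS experiment 2 out, and 2 other lists, chaperones and cytoskeleton, with the position trend removed. For nitroarginine against NMDA 0 became 1 with the position trend removed. For nitroarginine against control the 2 calls became 0 with both estimated correlation settings and with NOS experiment 2 out, and 1 with the block and the misaligned array out or moved, or 1 other list, ribosomal proteins, with the position trend removed. Leaving out 1 NOS set array without the block also puts the difference between experiments into the contrast. Leaving out 1 array each time, list calls ranged from 0 to 1 for NMDA over both sets, 0 to 0 for NMDA in the NOS set and for nitroarginine against control, and 0 to 1 for PD98059 against NMDA and for the NMDA difference between sets. The cause was not tested.

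The nitroarginine effect on probes that NMDA moved in the MEK set had a median on the highest probes of -0.0574 with median centring, 0.0728 with the misaligned array out, 0.0250 with NOS experiment 2 out too, and 0.0340 with NOS experiment 2 alone out. Leaving out single arrays gave -0.3762 to 0.4809. On the lowest probes, at 0.0878 as designed, it was -0.0127 with the misaligned array out, -0.0477 (percentile 0.12) with NOS experiment 2 out too, -0.0432 (percentile 1.03) with NOS experiment 2 alone out, -0.07732 without the dimmest 25% of probes, and -0.2036 to 0.3566 leaving out single arrays. The ends of the single-array ranges left out 1 NOS set array, which puts the difference between experiments into the median. The cause of the other changes was not tested.

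None of the named values that changed sign had passed a test. For NMDA in the MEK set Map7d1 was at -0.241 with the column moved, with and without the block, -0.00699 with the block and the column out (also with trend and robust), and -0.00492 with the position trend removed. For PD98059 against control it was at -0.251 with the column moved, with and without the block, -0.00903 with the column out (also without NOS experiment 2), -0.0171 with the block too (also with trend and robust) and -0.0140 with PD98059 crossed. Ntm was at -0.0478 with the column moved, with and without the block, and Cand1 at -0.0127 with probes of a gene averaged. For nitroarginine against control without NOS experiment 2 Poll was at -0.0128, Xpr1 at -0.107, Dscam at 0.0622 and Sez6 at 0.0443. In the difference between sets COX3 was at -0.141 with probes averaged and Mtcp1 at 0.0298 without NOS experiment 2. For Map7d1 and Ntm the designed value was in part a difference between unlike probes, through the misaligned column. The cause of the other sign changes was not tested. Leaving out 1 array each time, values ran from -0.0303 to 0.754 for Hspa8, -0.0339 to 0.741 for Xpr1 and -0.0246 to 0.488 for Eif4g1 (nitroarginine against control), from -0.00903 to 3.04 for Map7d1 (PD98059 against control), and from -0.00333 to 1.48 for Chpf and -0.0263 to 1.16 for Ap2m1 (inhibitor difference). A value without 1 NOS set array also holds the difference between experiments. The upper end for Map7d1 rests on the misaligned column.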

Other observations

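Between the NMDA, inhibitor and knockout arrays, Slc6a8, the creatine transporter gene, had the knockout value farthest below 0 among the named brighter probes (-0.76). Under NMDA it was at -0.26 in MEK experiment 2, -0.22 in NOS experiment 1 and 0.24 in NOS experiment 2. Dpysl5 was low in the knockout (-0.63) and under NMDA in MEK experiment 2 (-0.75) and NOS experiment 1 (-0.41), with 0.08 in NOS experiment 2. Vars was at -0.57 in the knockout on a probe outside the knockout rule, and at -0.76, -0.37 and -0.26 under NMDA. None of the knockout values has a replicate. Across the 3 NMDA experiments with an aligned control, 295 probes had 1 sign (189 higher, 106 lower), which is 25.6% where 25% would by chance. The pairs of experiments differ. Across probes, which are not independent replicates, the NMDA differences of MEK experiment 2 correlated at r = 0.21 with NOS experiment 1 (0 of 1104 rotations of the probe order as large) and at 0.17 with MEK experiment 1 with its control column moved by 1 row (0 of 1103). With NOS experiment 2, r was -0.05 for MEK experiment 2 and 0.02 for NOS experiment 1.

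The tests below were chosen after the result was seen, except the partial correlation of the knockout and the removal of the running median in NOS experiment 2. The first pattern is that MEK set control replicate 1 hardly correlates with any array as deposited. RNA of another tissue alone is argued against as the cause of these low r. The highest r of this array with another was 0.127. Adult mouse cortex, another tissue of another species, reached 0.730 or more with every aligned MEK set array. A column 1 row from its probes has a low r whatever its RNA, so this test cannot tell the source of the RNA. A shift by 1 row gave r = 0.822 with the median array, consistent with values that stand 1 row from their probes. Moved, it still correlated less with the MEK set (0.858 to 0.868) than these arrays did with each other, and that remainder stays open. No biological explanation was tested.

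The second pattern is that NMDA minus control differences of NOS experiment 2 run together along the probe order. Their lag 1 autocorrelation was 0.496, against 0.1495 and 0.119 in the other aligned experiments, which is consistent with noise that follows probe position. A smooth trend that hides a response shared with NOS experiment 1 stays open. After a running median was removed, the NMDA differences of both NOS experiments correlated at r = -0.0404, so no shared response appeared. The differences spread more in experiment 2 (SD 0.44 against 0.13 before that removal). Noise in either difference lowers r. The SDs do not show how much of the wider spread is noise, so the test cannot exclude a shared response. No biological explanation was tested, and a difference between the cultures may remain.

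The third pattern is the resemblance of the knockout differences to those of nitroarginine in NOS experiment 1 (r = 0.50 across probes). A component common to unrelated array pairs as the whole cause stays open. The partial r was 0.381 given NMDA minus control of MEK experiment 2, the probe level and the running median. It cannot exclude such a component, because 1 difference between single arrays holds it only in part and with noise. Loss of nitric oxide signalling stays open. Of the 5 differences that involve no NOS inhibitor, the one with the highest r with the knockout was that of MEK experiment 2 (0.357), and the others had -0.15 to -0.008, so the values point both ways. With 1 mouse per genotype, the animals themselves also stay open.

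For NMDA over both sets, the 8 control and NMDA arrays were also split in other ways into 4 and 4, in a fit with 1 common split effect beside set and inhibitor, which counts 8 probes at an unadjusted p under 0.05. Of 35 splits 34 could be fitted. At the adjusted threshold the real split had 0 probes and the highest other 0, so that all 34 had as many by construction and this count decides nothing. At an unadjusted p under 0.05, 14 splits, the real one included, had as many, and the highest other had 399. With experiment as a block the real split had 0 adjusted calls and the highest other 18. At an unadjusted p under 0.05 it had 44, 10 splits with it had as many, and the highest other had 462. Counts this far above the real one point to a structure of the arrays other than treatment: the splits with 399 set both NOS experiment 2 arrays, 1 NOS experiment 1 array and the misaligned column against the rest. Of the 8 splits that, like the real one, part control from NMDA in all 4 experiments, the highest other had 6 (32 with the block). These 8 are too few for a share under 0.05.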
